A study of Homo sapiens with 6 samples.

How the data were processed

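Total RNA was extracted with Trizol from 6 BeWo samples, labelled as biotinylated cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The 2 groups were untreated cells and cells exposed to 250 µM 8-Br-cAMP for 24 h, with 3 arrays each, taken from the labels' treatment entry. The submitters' processing notes name MAS5 and Affymetrix Expression Console; their versions, and the genome build behind the probe sets, are not given in the sources used here.

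The deposited table holds one linear intensity (a MAS5 signal) per probe set and array, which the authors computed before deposit, for 54675 probe sets. All values were above 0. On each array the mean after trimming 2% at each end was about 500 (500.1 on all arrays), so each array had been scaled to a common target; no further normalization between arrays was visible. MAS5 signals near the background are noisy on a log scale, and one scale factor per array assumes a similar total signal in both groups. Detection calls and scanner files were not used here. The maximum signal was 48655 to 67671 across arrays. No 2 arrays held the same values.

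Probe sets were named through the platform annotation of 2016 given with the series: 41091 probe sets had 1 gene symbol, 1801 several and 11721 none, besides 62 control probe sets. Of those with 1 symbol, 41037 matched a RefSeq gene by Entrez identifier, and no symbol needed updating. A gene was represented by its probe set with the highest mean log2 signal over the 6 arrays, which gave 19775 genes. Of these, 11888 had a mean log2 signal at or above the median of all non-control probe sets (5.75, a signal of 53.7) and were tested. Among 5872 genes with more than 1 probe set above the filter, 84 had probe sets called in opposite directions, and none of these is a named gene. Of 36 named and called genes with several such probe sets, 22 had all of them called the same way. No coordinates are given because no build was named.

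Tests used limma 3.58.1 in R 4.3.3 on log2(signal) with no pseudocount: lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the genes tested. Fold changes are ratios of geometric means, with standard errors from limma; group values are arithmetic means ± SD of signals. Single values per array were compared by exact permutation, which cannot give a p below 0.1 with 3 arrays against 3. For 19 gene lists fixed before the data were examined, camera with a preset inter-gene correlation of 0.01 compared each list with all other tested genes, adjusted over the 18 lists with at least 5 tested members. Listed genes below the filter or without a probe set of their own are outside the counts of each list. Of 346 tested genes on the lists, 8 were on more than 1. Named genes followed a rule also fixed before the data were examined: the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, the 3 members of each list with the largest change among those called (filled up by smallest adjusted p), and a fixed set of trophoblast genes. Other list members given in the text are examples chosen after their values were seen. CGB3 and TP63, of the fixed set, had no probe set paired with them alone.

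The code was tested on simulated arrays with the means and spread of these data and 200 of 11888 genes changed. It recovered 55% of genes changed by 0.5 and 80% of those changed by 1 on the log2 scale, with 3.57% false among the called, and called both of the 2 shifted lists and 0 of the others. Far fewer genes changed in it than the 3899 called in the real data, and its noise followed limma's own model. These shares are therefore a check of the code and do not carry over to the real calls. Every member of the shifted lists moved by 0.5 with no other gene changed, which is an easy case. The noise was drawn independently for each gene, so the simulation cannot show how camera treats lists whose genes vary together. In the real data the estimated correlation was 0.227 for the list of syncytiotrophoblast hormones.

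Alternatives chosen before the data were examined were quantile normalization, median centring, log2(signal + 16), no filter, a filter at the 70th percentile, eBayes without the trend or robust, the replicate number as a block, the mean of all probe sets of a gene, no probe sets with shared sequence, leaving out each array in turn, camera with an estimated correlation, and fry, which asks a different question, whether a list changed at all. Arrays were left out with the probe sets and tested genes kept as chosen over all 6. Scaling to 9 hybridization spike-in or 12 poly-A spike-in probe sets, the transcription factor list without OVOL1, the test of bright probe sets without CGA, and the RNA quality slopes over other genes than those called, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.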

Results

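Gene expression was measured in BeWo cells, a human choriocarcinoma line used as a model of placental trophoblast, whose mononucleated cells fuse into a multinucleated layer, the syncytiotrophoblast, when cyclic AMP rises. Of the 6 arrays, 3 came from untreated, undifferentiated cells and 3 from cells exposed for 24 h to 250 µM 8-Br-cAMP, a cell-permeable analog of cyclic AMP. Each array was an Affymetrix expression array hybridised with biotinylated cRNA made from 6 µg of total RNA, and its values were MAS5 signals on a linear scale. The median signal over probe sets was 66.1, 62.9 and 63.8 on untreated arrays 1 to 3, and 60.1, 55.3 and 58.5 on 8-Br-cAMP arrays 1 to 3. The number of arrays limits the precision of every value given here. Nothing in the labels says that the 3 arrays of a group came from separate cultures. The p-values for single genes therefore measure only the spread between these arrays, which may be technical. Camera with its preset correlation sets a list against the spread over genes. Its p-values rest on the number of genes and say little on how a change repeats between cultures. Over probe sets, Pearson's r between arrays was 0.981 to 0.984 within a group and 0.967 to 0.971 between groups; these values are across probe sets, which are not independent replicates.

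The comparison asked which genes change when BeWo cells are pushed from the undifferentiated state by a cyclic AMP analog. After 8-Br-cAMP, OVOL1, a zinc finger transcription factor of epithelial differentiation, rose 5.95-fold, from a signal of 1446 ± 111 to 8608 ± 631 (SD, n = 3 arrays per group throughout). Its paralog OVOL2 fell, from 1095 ± 76.1 to 229 ± 51.5. The endogenous retroviral envelope gene of syncytin-2 (ERVFRD-1) was higher. So were 10 of 14 tested genes on a steroid hormone list, which also holds a receptor and a cortisol-inactivating enzyme. Of 18 targets of cyclic AMP and CREB, 13 were higher, and of 30 mitosis genes, 24 were lower. A probe set shared by 5 chorionic gonadotropin beta genes, which encode the pregnancy hormone's specific subunit, rose from 3698 ± 588 to 21044 ± 1878, a log2 change of 2.52 ± 0.10 (standard error, adjusted p = 7.53e-08 in limma); it cannot be assigned to any 1 of them.

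Among 11888 genes tested with limma, 3899 passed an adjusted p of 0.05, which is 32.8% of them. Of these, 1737 were higher and 2162 lower after 8-Br-cAMP, so that 44.5% of the called genes were higher. At least a 2-fold difference was seen in 216 higher and 186 lower genes. The groups did not overlap for 5454 tested genes, 45.9% against 10% by chance, and for 3815 of the called genes. The split between higher and lower calls depended on how the arrays were scaled. It was 2824 higher and 1068 lower with median centring (72.6% higher), 898 and 3797 with scaling to the hybridization spike-ins (19.1%), and 444 and 283 with scaling to the poly-A spike-ins (61.1%). The median log2 change of all tested genes was −0.06 as deposited; median centring moved every change by 0.15 and the hybridization spike-ins moved it by −0.15. Small changes are therefore relative to the scale of the deposited values. The gene list tests compare a list with all other tested genes on the same arrays, but some of their calls moved with the scaling too. With median centring, DNA replication became called (camera adjusted p = 0.025) and epithelial junctions lost their call (0.0826). The beta-actin 3′/5′ signal ratio, a measure of RNA integrity, was 2.57 ± 0.318 on untreated and 3.46 ± 0.755 on 8-Br-cAMP arrays, with 4.33 on 8-Br-cAMP array 3 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). This ratio moves with the treatment beside each gene group described here. The GAPDH ratio was 0.922 ± 0.0256 and 0.932 ± 0.00631 (exact permutation p = 0.5). Without 8-Br-cAMP array 3, 1381 genes were higher and 1749 lower.

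Of the 10 largest rises, PRR9, a proline-rich gene of the epidermal differentiation cluster, led, rising from 136 ± 31.1 to 1482 ± 75.8 (log2 change 3.47 ± 0.15, adjusted p = 6.75e-08). CRIP2, a LIM domain protein, rose from 65.3 ± 16.3 to 527 ± 25.3 (log2 change 3.04 ± 0.21). MMP12, the macrophage metalloelastase, rose from 48.5 ± 16.9 to 344 ± 37.1 (2.88 ± 0.28). GREB1, an estrogen-responsive gene, rose 7.21-fold, from 125 ± 20.3 to 895 ± 56.0 (adjusted p = 1.82e-07). OVOL1 had a log2 change of 2.57 ± 0.07 with a 95% confidence interval of 2.41 to 2.73 (adjusted p = 6.77e-09), and its dimmer probe set changed by 2.36. The other 5, like MMP12, had mean signals under the filter of 53.7 in untreated cells, from 26.4 to 50.9, so their fold changes rest on low signals. These 5 were RHOV, an atypical Rho GTPase, at a log2 change of 2.76 ± 0.67, the growth factor FGF18 at 2.73 ± 0.59, the zinc finger gene ZNF771 at 2.64 ± 0.48, OAF at 2.62 ± 0.57 and AQP2, the vasopressin-regulated water channel of the kidney, at 2.61 ± 0.31. Single untreated arrays moved them: RHOV was at 3.73 without array 1 and 2.07 without array 2, FGF18 at 3.38 without array 1 and 1.90 without array 3, and OAF at 1.94 without array 1 and 3.41 without array 2. Their adjusted p-values ran from 7.06e-05 for AQP2 to 0.0086 for RHOV, whose call was lost without an intensity trend in the variance model (adjusted p = 0.0597, over all alternatives 1.24e-07 to 0.0597). Second probe sets of AQP2 (log2 change 0.90, adjusted p = 0.12) and FGF18 (1.74, adjusted p = 0.0739) did not pass the threshold.

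Of the 10 largest falls, 4 were bright in untreated cells. ST3GAL5, the synthase of ganglioside GM3, was 4.96-fold lower, at 825 ± 19.6 and 166 ± 1.33 (log2 change −2.31 ± 0.11, adjusted p = 1.32e-07). OVOL2 had a log2 change of −2.28 ± 0.16 (adjusted p = 1.39e-06), and its second probe set −1.36. ENC1, an actin-binding kelch protein, went from 1767 ± 93.6 to 441 ± 38.8 (−2.00 ± 0.09), and RNF144B, an E3 ubiquitin ligase, from 1295 ± 83.3 to 323 ± 14.0 (−2.00 ± 0.09). The remaining 6 had untreated signals from 162 to 220 and dropped to between 34.4 and 56.9, under the filter of 53.7 in all but CCDC141, so the size of these falls rests on low signals. DOCK8-AS1, an antisense transcript, had the largest fall (log2 change −2.93 ± 0.59, adjusted p = 0.0029), but −2.07 without 8-Br-cAMP array 3. Next came the pseudogene GTF2IP20 (−2.20 ± 0.39), whose probe set may also measure related copies. TTN, which encodes the sarcomere protein titin, followed at −2.16 ± 0.41, but its second probe set gave −0.29 (adjusted p = 0.465). HAVCR2, the immune receptor TIM-3, changed by −2.09 ± 0.35, the zinc finger gene ZNF76 by −2.03 ± 0.41 and CCDC141 by −1.95 ± 0.23.

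**Figure D1:**
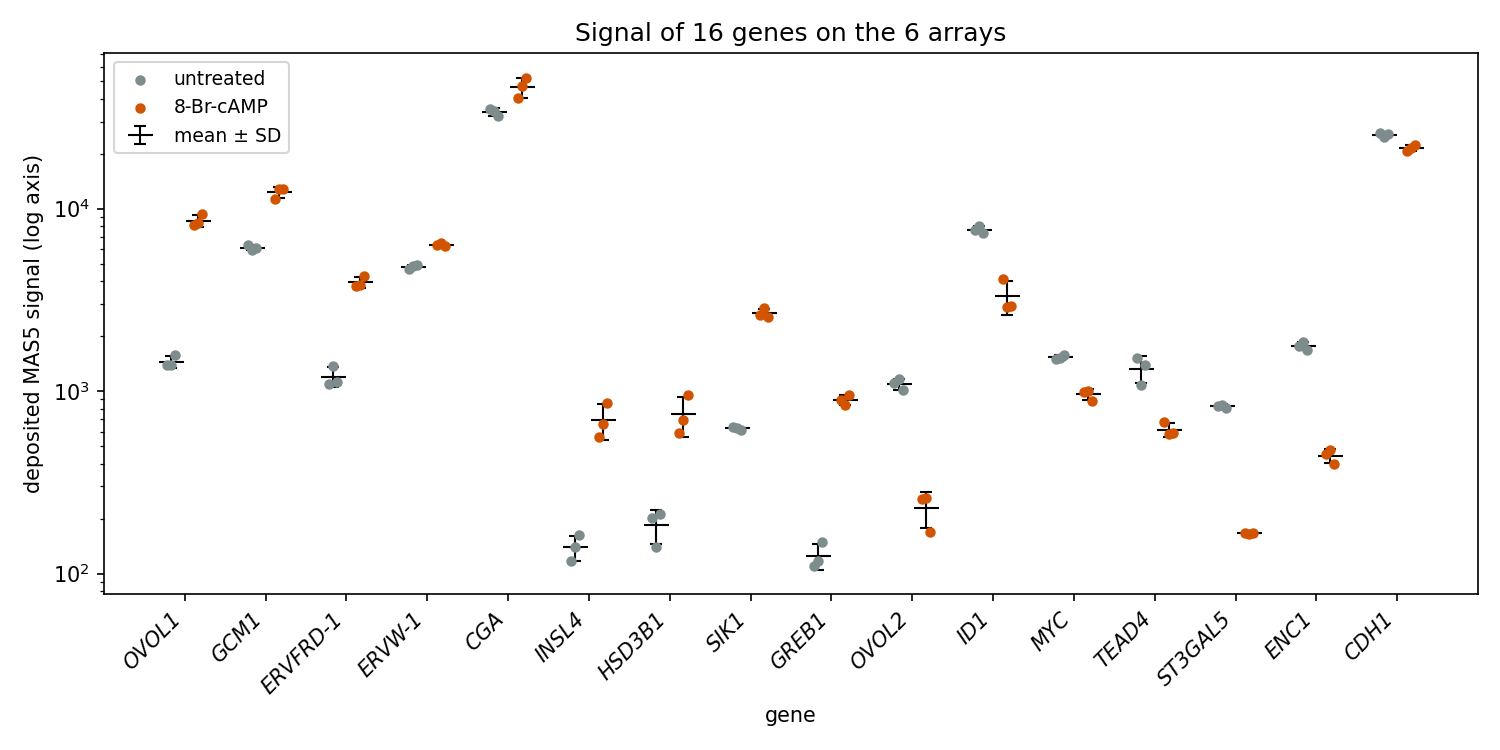
MAS5 signal (log axis) of selected named genes on each of the 3 untreated (grey) and 3 8-Br-cAMP (orange) arrays, with bars for mean ± SD. OVOL1 went from 1446 to 8608 and OVOL2 from 1095 to 229, with no overlap between groups, while the brighter probe sets of CGA and CDH1, drawn here, changed by 0.45 and −0.24 on the log2 scale and their dimmer ones, not drawn, by 2.38 and −0.76.

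Tested markers of the syncytiotrophoblast, the hormone-secreting fused layer of the placenta, mostly rose. Of 29 hormones and secreted proteins listed, 21 had a probe set of their own and 13 of these passed the filter. Members below it included INHBA, CRH, KISS1 and PAPPA. Of the 13 tested, 9 rose, 2 fell and 2 did not pass the test (10 and 2 adjusted over the list alone), with a median log2 change of 0.63. By camera the hormone list was higher (adjusted p = 3.27e-05; adjusted p = 0.139 with an estimated correlation). INSL4, an insulin-like peptide of early placenta, rose from 139 ± 22.0 to 693 ± 153 (log2 change 2.30 ± 0.18), placental growth factor PGF from 7828 ± 100.2 to 23994 ± 3383 (1.61 ± 0.09) and the TGF-beta family member GDF15 from 4889 ± 162 to 14000 ± 436 (1.52 ± 0.06). Leptin (LEP) changed by 1.29. CGA, the common alpha subunit of the gonadotropins, rose by 0.45 ± 0.09 on its brighter probe set, from 33856 ± 1613 to 46392 ± 5873 (adjusted p = 0.00313, over the alternatives 1.24e-05 to 0.263), and by 2.38 ± 0.08 on its dimmer one, from 469 ± 43.2 to 2441 ± 65.0. The members that fell were the placental lactogen genes CSH1 (−1.09) and CSHL1 (−0.84), which cannot be separated with certainty from their near-identical copies. Of 3 probe sets shared by CSH1 and CSH2, 1 passed the threshold (−0.56, adjusted p = 0.00136) and the others gave −0.20 and −0.23. SDC1, a surface proteoglycan of the syncytiotrophoblast, did not pass, with a log2 change of 0.10 ± 0.10 (adjusted p = 0.483) that was −0.05 with the hybridization spike-ins.

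Of 4 tested pregnancy-specific glycoproteins, secreted proteins of the syncytiotrophoblast, 2 passed the test as higher and 2 did not pass (2 and 0 adjusted over the list alone), too few for a list test. PSG9 rose from 66.5 ± 24.5 to 152 ± 14.9 (log2 change 1.25 ± 0.30, adjusted p = 0.00815), while PSG6 was marginal at 0.75 ± 0.26 (adjusted p = 0.0478, over the alternatives 0.0172 to 0.209). PSG4 was at −0.77 ± 0.63 (adjusted p = 0.382), a value that rested on 8-Br-cAMP array 1 and was 0.07 without it. Second probe sets of PSG9 (log2 change 2.11, adjusted p = 0.0151 in limma) and PSG6 (1.29, adjusted p = 0.0374) were called higher. So was a probe set shared by PSG3 and PSG11 (1.92, adjusted p = 0.00616), from a low untreated signal of 38.8 ± 22.4. The genes of this family are near-identical, so which member was measured is uncertain.

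Of 14 cell fusion genes, 7 rose, 2 fell and 5 did not pass (7 and 3 adjusted over the list alone), with a median of 0.24. The median was 0.39 with median centring (7 rose, 0 fell) and 0.09 with the hybridization spike-ins (5 rose, 4 fell). Fusion genes as a list were higher by camera (adjusted p = 0.0135; adjusted p = 0.139 with an estimated correlation). The fusogen syncytin-2 (ERVFRD-1) rose from 1200 ± 152 to 3947 ± 264 (log2 change 1.72 ± 0.09), a related retroviral envelope gene, ERVV-1, from 101 ± 43.3 to 238 ± 44.5 (1.30 ± 0.30), and GCM1, the transcription factor that drives syncytin expression, from 6097 ± 194 to 12301 ± 867 (1.01 ± 0.06). Syncytin-1 (ERVW-1) rose by 0.40 ± 0.05, from 4807 ± 130 to 6343 ± 109 (adjusted p = 1.57e-04, over the alternatives 5.84e-05 to 0.307). MFSD2A, the receptor of syncytin-2, and the gap junction gene GJA1 were below the filter. Their log2 changes were 2.08 ± 0.74 and 2.62 ± 0.89, with adjusted p = 0.0805 and 0.0675 when no filter was used. The size of these changes is uncertain, since the untreated signals were only 35.6 ± 37.1 for MFSD2A and 7.69 ± 6.76 for GJA1.

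Of 25 trophoblast transcription factors, 16 rose, 3 fell and 6 did not pass (16 and 3 adjusted over the list alone, 10 and 2 with the poly-A spike-ins), with a median of 0.43. As a list, these factors were higher by camera (adjusted p = 5.69e-08; adjusted p = 0.0285 with an estimated correlation). OVOL1 was listed with knowledge of the study and is not independent evidence; without it the median was 0.40 and the list was still higher (adjusted p = 1.56e-07 in the single fit made without it). Besides OVOL1 and OVOL2, the TEAD cofactor VGLL3 had the largest change, from 93.7 ± 4.87 to 342 ± 48.2 (log2 change 1.86 ± 0.18). SP6 rose by 1.84, DLX4 by 1.22 and TFAP2C by 0.67, while HAND1, a factor of early trophoblast, fell by 1.43 and PPARG by 0.25.

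Of 17 progenitor cytotrophoblast genes, 4 rose, 7 fell and 6 did not pass (5 and 7 adjusted over the list alone; 5 and 5 with median centring, 3 and 8 with the hybridization and 2 and 2 with the poly-A spike-ins), and the list did not pass (median −0.24, camera adjusted p = 0.528). Some of its members, MYC, ID1 and ASCL2 among them, were listed with knowledge of the study and are not independent evidence of a direction. The inhibitor of differentiation ID1 went from 7674 ± 313 to 3308 ± 693 (log2 change −1.23 ± 0.11), TEAD4, a transcription factor of trophoblast self-renewal, from 1329 ± 224 to 614 ± 53.7 (−1.10 ± 0.12), and MYC from 1533 ± 43.5 to 959 ± 69.5 (−0.68 ± 0.08, adjusted p = 4.90e-05). ID2, a close relative of ID1, went the other way, from 4834 ± 54.4 to 10771 ± 913 (1.15 ± 0.07). ASCL2 did not pass, at 0.26 ± 0.11 (adjusted p = 0.0874, over the alternatives 0.0134 to 0.952). It passed with median centring (0.41), without untreated array 3 (0.35) or without 8-Br-cAMP array 3 (0.36), and its value was −0.05 when all its probe sets were averaged. E-cadherin (CDH1) was lower by −0.24 ± 0.06 on its brighter probe set, from 25334 ± 637 to 21470 ± 815 (adjusted p = 0.0106, over the alternatives 4.30e-05 to 0.826), and missed the threshold without untreated array 1 (−0.23) or 3 (−0.23) and with median centring (−0.09). Its dimmer probe set fell by more, −0.76 ± 0.17, from 278 ± 40.8 to 163 ± 17.1 (adjusted p = 0.00732). TP63, a progenitor transcription factor, had no probe set paired with it alone and was not analysed here.

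Of 15 extravillous trophoblast genes, which mark the invasive branch of the lineage, 6 rose, 3 fell and 6 did not pass (6 and 3 adjusted over the list alone), with a median of 0.23. Camera called this list higher (adjusted p = 0.0135; adjusted p = 0.162 with an estimated correlation). The collagen-binding decoy receptor LAIR2 rose from 3202 ± 141 to 10751 ± 546 (log2 change 1.75 ± 0.06), the adhesion molecule MCAM from 372 ± 15.0 to 874 ± 86.1 (1.23 ± 0.10) and the serine protease HTRA4 from 7216 ± 903 to 16320 ± 1519 (1.18 ± 0.09). HLA-G, the best known marker of these cells, gave 0.04. The 3 members that fell were ITGA5 (−0.54), NOTCH2 (−0.46) and PLAC8 (−0.34). The list's camera call was lost when all probe sets of a gene were averaged (adjusted p = 0.183, over the alternatives 3.41e-04 to 0.183). It was also lost without probe sets of shared sequence (adjusted p = 0.0855).

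**Figure D2:**
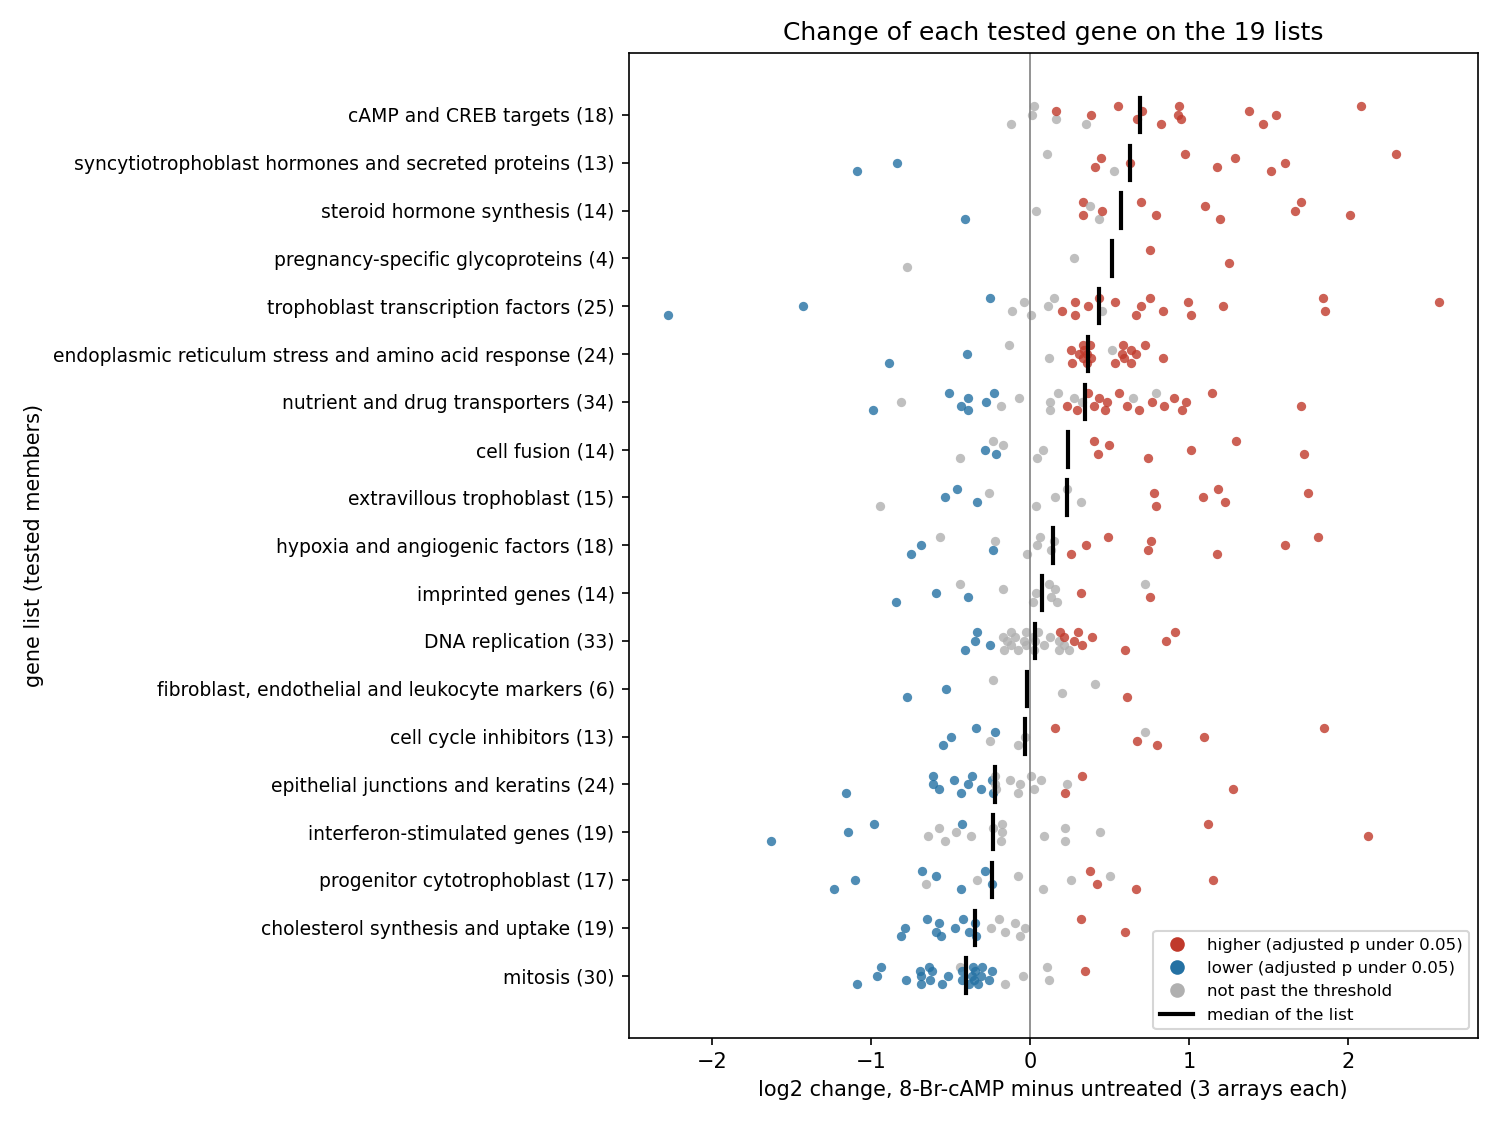
Log2 change (8-Br-cAMP minus untreated) of every tested member of the 19 gene lists, 1 point per gene, coloured by whether it passed an adjusted p of 0.05; black bars are list medians. Medians ran from −0.40 for mitosis to 0.69 for cAMP and CREB targets, and those of DNA replication, hypoxia, imprinted, cell cycle inhibitor and other cell type genes changed sign under another scaling.

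Cell cycle genes did not all move alike. Of 30 mitosis genes, 24 fell, 1 rose and 5 did not pass (25 and 1 adjusted over the list alone), with a median of −0.40. The counts lower and higher were 15 and 2 with median centring, 25 and 1 with the hybridization spike-ins, and 4 and 0 with the poly-A spike-ins, where the median was −0.35. The list was lower by camera (adjusted p = 4.21e-09; adjusted p = 0.0347 with an estimated correlation). The spindle checkpoint kinase BUB1B went from 4131 ± 159 to 1949 ± 177 (log2 change −1.09 ± 0.07), the kinetochore protein CENPF from 4806 ± 82.7 to 2469 ± 102 (−0.96 ± 0.06) and the cytokinesis motor KIF23 from 1436 ± 40.1 to 753 ± 86.4 (−0.94 ± 0.09). The proliferation marker MKI67 was the 1 that rose, by 0.35, and CCNB1 (0.12) and AURKA (0.11) did not pass. Of 33 DNA replication genes, 9 rose, 4 fell and 20 did not pass (10 and 4 adjusted over the list alone). Their median was 0.03, turning to −0.12 with the hybridization spike-ins, −0.0065 without untreated array 1 and −0.0047 without 8-Br-cAMP array 1, and the list did not pass (camera adjusted p = 0.0866, over the alternatives 6.78e-04 with fry to 0.253). RRM2, a subunit of ribonucleotide reductase, rose from 14928 ± 14.5 to 28214 ± 3574 (0.91 ± 0.08), and cyclin E genes rose, CCNE1 from 13223 ± 217 to 24030 ± 2061 (0.86 ± 0.07) and CCNE2 from 1549 ± 27.4 to 2341 ± 99.1 (0.60 ± 0.06). Helicase subunits MCM2 (−0.25), MCM3 (−0.35) and MCM5 (−0.33) fell. Mean log2 signal of the mitosis genes minus that of the replication genes was 0.38, 0.40 and 0.35 on untreated arrays and −0.11, −0.15 and −0.16 on 8-Br-cAMP arrays (two-sided exact permutation p = 0.1, the smallest possible). Of 13 cell cycle inhibitors, 5 rose, 4 fell and 4 did not pass (6 and 4 adjusted over the list alone). Their median was −0.03 (0.12 with median centring, 0.03 with the poly-A spike-ins), while their mean was 0.26 and the camera direction up, and the list did not pass (camera adjusted p = 0.232, over the alternatives 1.96e-04 with fry to 0.414); by camera it passed as higher with the poly-A spike-ins. Calls higher and lower were 6 and 2 with median centring and 3 and 5 with the hybridization spike-ins. MXD1, a MYC antagonist, rose from 574 ± 51.6 to 2066 ± 21.3 (1.85 ± 0.08), and the stress gene GADD45G from 315 ± 6.80 to 672 ± 36.0 (1.09 ± 0.10). GADD45B was at 0.80 ± 0.27 (adjusted p = 0.044, over the alternatives 0.00486 to 0.356). CDKN1A, the inhibitor p21, rose by 0.67, and RBL2 fell by 0.50.

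**Figure D3:**
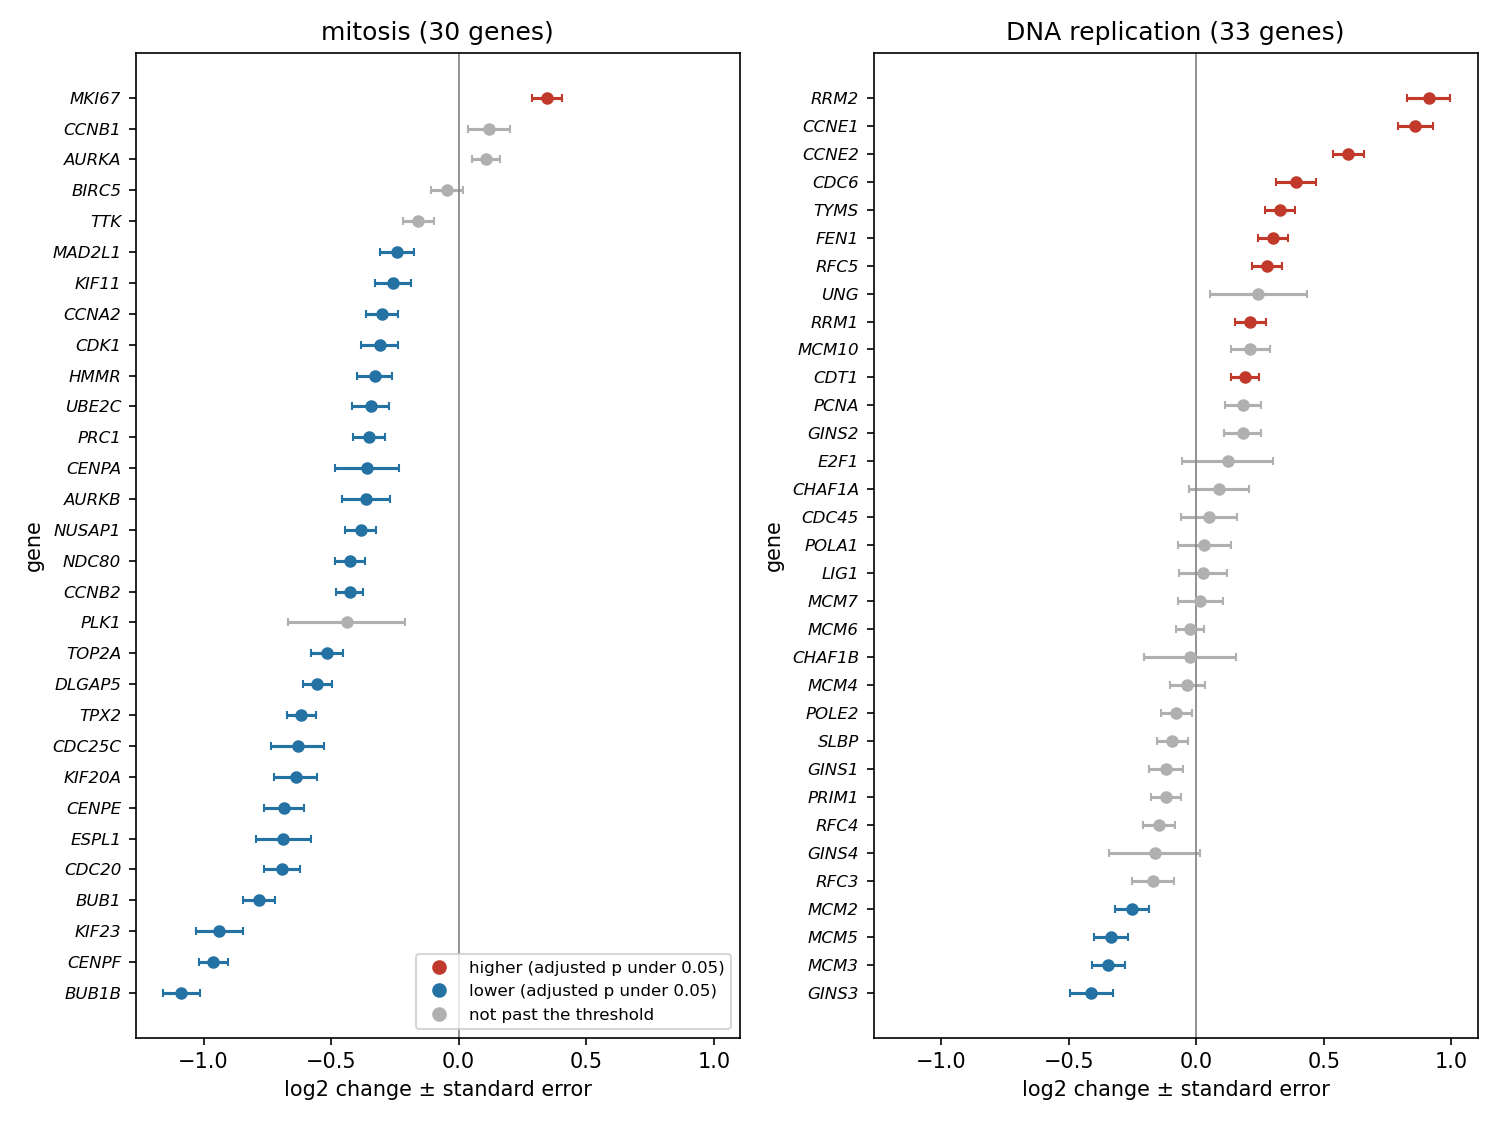
Log2 change (8-Br-cAMP minus untreated) with its standard error for each tested mitosis gene (left, 30 genes) and DNA replication gene (right, 33 genes), coloured by direction for genes past an adjusted p of 0.05. Mitosis genes lie mostly below 0, with 24 called lower, whereas 9 replication genes were called higher and 4 lower on the deposited scale (12 and 0 with median centring, 4 and 11 with the hybridization spike-ins).

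Genes of the cyclic AMP response rose. Of 18 tested cAMP and CREB targets, 13 rose, 0 fell and 5 did not pass (14 and 0 adjusted over the list alone), with a median of 0.69. The list was higher by camera (adjusted p = 4.21e-09; adjusted p = 0.0285 with an estimated correlation). The salt-inducible kinase SIK1 rose from 628 ± 11.4 to 2664 ± 163 (log2 change 2.08 ± 0.07), the G protein regulator RGS2 from 239 ± 11.8 to 700 ± 58.2 (1.55 ± 0.12), and the cyclic AMP phosphodiesterase PDE4D from 357 ± 24.8 to 985 ± 55.9 (1.46 ± 0.10) with 4 of 4 probe sets called. FOSB rose by 1.38 and CREM by 0.94.

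Of 14 steroid hormone genes, 10 rose, 1 fell and 3 did not pass (10 and 1 adjusted over the list alone), with a median of 0.58. The list was higher by camera (adjusted p = 5.50e-07; adjusted p = 0.0351 with an estimated correlation). HSD3B1, which makes progesterone from pregnenolone, rose from 184 ± 38.9 to 745 ± 184 (log2 change 2.01 ± 0.20), the orphan receptor ESRRG from 49.9 ± 22.3 to 153 ± 26.7 (1.70 ± 0.37; second probe set 0.66, adjusted p = 0.111) and the cortisol-inactivating enzyme HSD11B2 from 98.7 ± 16.4 to 315 ± 66.5 (1.67 ± 0.21). CYP11A1, the side-chain cleavage enzyme, rose by 1.19 and aromatase CYP19A1 by 1.10. Cholesterol synthesis and uptake genes mostly fell: 11 of 19, with 2 higher and 6 not past the test (12 and 2 adjusted over the list alone), and a median of −0.34. The list was lower by camera (adjusted p = 0.00145; adjusted p = 0.102 with an estimated correlation). The sterol reductase TM7SF2 went from 186 ± 4.33 to 106 ± 8.74 (−0.81 ± 0.20), the sterol regulator SREBF2 from 406 ± 83.8 to 235 ± 47.5 (−0.79 ± 0.19) and HMGCS1, of the mevalonate pathway, from 5713 ± 220 to 3643 ± 138 (−0.65 ± 0.06). None of the 19 list members passed with the poly-A spike-ins, where the median was −0.29 and the list was still lower by camera (adjusted p = 0.0145, over the alternatives 1.05e-04 to 0.102). As deposited, 2 of the 3 probe sets of SREBF2 did not pass. HMGCR and LDLR had no probe set of their own and were not analysed here.

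Of 34 nutrient and drug transporters, 17 rose, 7 fell and 10 did not pass (18 and 7 adjusted over the list alone), with a median of 0.35. With the hybridization spike-ins 12 rose and 7 fell (median 0.20), and with the poly-A spike-ins 6 and 1 did (median 0.41). The list was higher by camera (adjusted p = 2.32e-04; adjusted p = 0.0385 with an estimated correlation). The glutamine transporter SLC38A3 rose from 32.4 ± 2.64 to 107 ± 23.7 (log2 change 1.71 ± 0.35), the iron exporter SLC40A1 by 0.98 and the arginine transporter SLC7A1 by 0.95. The serotonin transporter SLC6A4 was at 1.15 ± 0.40 (adjusted p = 0.0447, over the alternatives 0.0125 to 0.187), and at 0.74 without 8-Br-cAMP array 1. The sulfate transporter SLC26A2 went from 629 ± 55.4 to 317 ± 20.9 (−0.99 ± 0.12).

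Genes of the endoplasmic reticulum stress and amino acid response rose by small steps. Of 24 tested, 19 rose, 2 fell and 3 did not pass (19 and 2 adjusted over the list alone), with a median of 0.37. With the hybridization spike-ins 12 rose and 3 fell, with a median of 0.22, and with the poly-A spike-ins 5 and 1 did, with a median of 0.43. The list was higher by camera (adjusted p = 2.36e-08; adjusted p = 0.0389 with an estimated correlation). HERPUD1, of endoplasmic reticulum associated degradation, rose from 7169 ± 275 to 12812 ± 996 (log2 change 0.84 ± 0.07) and the chaperone DNAJB9 from 2539 ± 87.1 to 4203 ± 280 (0.73 ± 0.06). The chaperone HSPA5 rose by 0.58, and the lipoprotein receptor VLDLR fell, from 1470 ± 87.8 to 794 ± 64.7 (−0.89 ± 0.08). Of 24 epithelial junction and keratin genes, 11 fell, 3 rose and 10 did not pass (12 and 4 adjusted over the list alone), with a median of −0.22. The list was lower by camera (adjusted p = 0.0319; adjusted p = 0.162 with an estimated correlation, over all alternatives 5.38e-04 with fry to 0.218), and its call was lost without untreated array 2 (median −0.18) or 8-Br-cAMP array 1 (−0.24). Calls lower and higher were 4 and 4 with median centring, where the median was −0.07 and the list call was lost, 17 and 1 with the hybridization spike-ins, and 1 and 1 with the poly-A spike-ins, where it was lost too. The tight junction proteins cingulin (CGN), from 1238 ± 45.2 to 555 ± 20.9 (−1.16 ± 0.08), and occludin (OCLN), from 2673 ± 57.3 to 1750 ± 89.4 (−0.61 ± 0.06), were lower, as were claudins CLDN3 (−0.61), CLDN4 (−0.48) and CLDN6 (−0.43). Keratin 23 (KRT23) rose from 1018 ± 128 to 2461 ± 210.4 (1.28 ± 0.10).

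Of 18 hypoxia and angiogenic genes, 8 rose, 3 fell and 7 did not pass (8 and 3 adjusted over the list alone), with a median of 0.14 that was −0.0072 with the hybridization spike-ins. The list was higher by camera (adjusted p = 0.0135; adjusted p = 0.124 with an estimated correlation). NDRG1, a stress-responsive gene, rose from 369 ± 112 to 1256 ± 131 (log2 change 1.81 ± 0.19), the vasodilator peptide adrenomedullin (ADM) from 5707 ± 115 to 12894 ± 585 (1.18 ± 0.06) and VEGFA by 0.74, while LDHA (0.15), PGK1 (0.05) and FLT1 (0.13) did not pass. Interferon-stimulated genes did not move together: of 19 tested, 2 rose, 4 fell and 13 did not pass (2 and 4 adjusted over the list alone, 2 and 8 with the hybridization spike-ins; median −0.24, camera adjusted p = 0.411). The antiviral enzyme RSAD2 rose from a mean of 163 to one of 714 (2.13 ± 0.14), whereas the RNA sensor RIGI went from 345 ± 41.6 to 155 ± 2.59 (−1.15 ± 0.16). The RNA sensor IFIH1 was at −1.63 ± 0.41 (adjusted p = 0.0104, over the alternatives 0.00463 to 0.0504) and missed the threshold without untreated array 1 (−1.49). STAT1 and STAT2, also listed, had no probe set that the annotation pairs with 1 of them alone and were not tested. A control probe set outside the tests measures STAT1 under its older name, ISGF3A. Its 3′ signal went from 3222 ± 75.5 on untreated to 1806 ± 57.2 on 8-Br-cAMP arrays. Of 14 imprinted genes, 2 rose, 3 fell and 9 did not pass (3 and 3 adjusted over the list alone; 6 and 2 with median centring, 1 and 4 with the hybridization spike-ins), with a median of 0.08 (−0.07 with the hybridization spike-ins), a mean of the other sign, −0.0006, and no call (camera direction up, adjusted p = 0.528). PHLDA2, a growth-restricting placental gene, rose from 8665 ± 391 to 14647 ± 1320 (0.75 ± 0.07), PPP1R9A went from 645 ± 85.2 to 357 ± 24.6 (−0.85 ± 0.12) and PEG10 from 1797 ± 179 to 1187 ± 58.4 (−0.59 ± 0.08).

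Markers of fibroblasts, endothelium and leukocytes gave no sign of a common shift. Of 22 listed, 20 had a probe set of their own and 6 of these passed the filter: 1 rose, 2 fell and 3 did not pass (1 and 2 adjusted over the list alone), and the median was −0.02, or 0.13 with median centring, 0.11 with quantile normalization and 0.04 with the poly-A spike-ins (camera adjusted p = 0.665). Collagen gene COL1A1 was at 0.61 ± 0.07 on its brightest probe set, and its 3 others did not pass. Smooth muscle actin (ACTA2) went from 512 ± 32.2 to 299 ± 9.03 (−0.77 ± 0.11) and TAGLN, a smooth muscle actin-binding protein, from 1141 ± 111 to 790 ± 20.6 (−0.53 ± 0.09).

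Across the 18 lists tested, 9 were higher and 3 lower. With an estimated correlation, transcription factors, cAMP targets, steroid hormone genes, transporters and the endoplasmic reticulum response were still higher and mitosis still lower. No called list member changed sign under another scaling. With the poly-A spike-ins, whose log2 signal had an SD of 0.30 among untreated arrays and which moved every change by 0.06 only, the calls of CGA, ERVW-1, MYC, CDH1, CCNE2, HMGCS1, SREBF2, TM7SF2, OCLN, PEG10, ACTA2, TAGLN, COL1A1, PSG6 and SLC6A4 were lost. When all probe sets of a gene were averaged, those of CCNE1 (log2 change 0.51), HSD3B1 (1.18), VGLL3 (1.23), MCAM (0.71), SREBF2 (−0.42), PPP1R9A (−0.51), COL1A1 (0.28), PSG6 and GADD45B were lost, and the changes of GDF15 (0.77) and SIK1 (1.22) were smaller. When probe sets with shared sequence were left out, PHLDA2 changed less (0.36) and lost its call, while TAGLN (−0.71) and GADD45B (0.80) lost theirs without a smaller change.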

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

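The test of the array scaling, and the RNA quality slopes over other genes than those called, were chosen only after the results were seen. Probe sets without a single gene symbol are outside the gene comparison, and 45 of the 5021 above the filter were at least 2-fold higher after 8-Br-cAMP and past the threshold, with 99 at least 2-fold lower; these drew attention as signal that no gene result covers.

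The first pattern is the large number of genes called, 3899 of 11888, with 44.5% of them higher, a balance the scaling of the arrays can account for, since it was 72.6% with median centring and 19.1% with the hybridization spike-ins. As a test of RNA quality as the cause of the changes as a set, the slope of the difference between 8-Br-cAMP arrays 3 and 2 on the change of array 1 was 0.00669 ± 0.00763 (standard error) over all tested genes and −0.0496 ± 0.0068 over 3130 genes called without array 3, where a change following the beta-actin ratio needs at least 1.01. Both were added because the first form of the test, 0.028 ± 0.0059 over the called genes, is favoured by calling genes on which the arrays agree. The 3130 genes were still chosen with arrays 1 and 2, which both enter the slope, so a slope near or below 0 is favoured there too. Noise on array 1 lowers the slope over all tested genes. A further slope, of the change on array 3 on the mean change on arrays 1 and 2, was 0.949 ± 0.0061. The beta-actin ratio gives 3.11 for it. That slope rests on array 3 alone, and the untreated arrays that enter both sides pull it toward 1. These slopes therefore cannot settle how far RNA quality contributed. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many called genes, and the highest other gave 0, but 10 splits are too few for a share under 0.05. The treatment named by the design stays among the open explanations of the calls, and a difference in culture or processing between the groups was not tested.

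The second pattern is that 24 of 30 mitosis genes were lower and 1 higher, while of 33 DNA replication genes 4 were lower and 9 higher (11 and 4 with the hybridization spike-ins). The gap between the list medians was −0.44, below −0.16, the 2.5th percentile of 10000 pairs of random lists matched on mean signal, which argues against a signal-dependent shift of the arrays. Because it is a difference between lists on the same arrays, a scale factor per array leaves it as it is. A hypothesis is that 8-Br-cAMP may shift the cells in the cell cycle, with fewer cells in mitosis; these arrays hold no count of cells by phase, and this was not tested.

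The third pattern is that the brighter probe set of CGA changed by 0.45 and the dimmer one by 2.38. A ceiling of the signal on the brightest probe sets was tested: the median ratio of the brighter to the dimmer probe set's change was 0.586 in 11 genes with a signal above 20000 and 0.695 in 219 genes from 2000 to 8000, a difference of −0.109 (one-sided permutation p = 0.173). CGA, which prompted the test, is among the 11, and without it, in a test added after the result was seen, the difference was −0.0822 (one-sided permutation p = 0.256). So few bright genes leave the ceiling open. A difference between the transcripts that the probe sets measure was not tested.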

How the results depend on the processing

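The spike-in scalings were added after seeing the data. No named gene or list was called in the opposite direction, but the share of called genes that were higher, 44.5%, was 72.6% with median centring and 61.1% with the poly-A spike-ins, and several list medians near 0 changed sign. Counts moved by more than 1.5 times in these cases, and except where the construction shows it the cause was not tested. Genes higher were 2824 with median centring, 935 with the mean of all probe sets, 898 with the hybridization and 444 with the poly-A spike-ins, against 1737. Genes lower were 1068, 1412, 3797 and 283 with the same settings, against 2162. Genes at least 2-fold lower were 123 with quantile normalization, 103 with median centring, 74 with the stricter filter (fewer genes tested) and 384 with the hybridization spike-ins, against 186, and genes at least 2-fold higher were 135 with the stricter filter, against 216. Camera with an estimated correlation called 5 lists higher and 1 lower, against 9 and 3; fry, which tests a list against no change and not against other genes, called 11 and 3. The other 97 counts lay within 1.5 times, including every array left out (2957 to 4081 genes called). For lists, 336 outcomes were on the same side of the threshold, 18 weaker and 5 stronger; for named genes 1317, 56 and 3, with 15 of the weaker ones under the poly-A spike-ins. The replicate numbers do not pair the arrays (correlations of deviations −0.0045, −0.036 and −0.018, and no array correlated best with its own number); with the replicate block 1580 genes were higher and 1982 lower, and 1 named gene, PSG6, missed the threshold. Of lists, hypoxia missed the threshold with quantile normalization (adjusted p = 0.078, over the alternatives 4.65e-04 with fry to 0.276) and cell fusion with the stricter filter (0.0595, over the alternatives 4.65e-04 with fry to 0.139). Without shared-sequence probe sets, the camera calls of hypoxia (median 0.02, adjusted p = 0.276), extravillous trophoblast (0.0855) and epithelial junctions (0.110) were lost. DNA replication passed camera with median centring and with no filter, and cell cycle inhibitors with the poly-A spike-ins; both passed fry's different test. Low signals limit the dim genes: untreated signals of 6 of the 10 largest rises were under the filter, and so were those of SLC38A3, ESRRG and SLC6A4.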

Other observations

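Genes outside the naming rule, chosen after their values were seen, include several bright ones. The neutral amino acid transporter SLC6A19 rose from 540.4 ± 108 to 3053 ± 189 (log2 change 2.52 ± 0.12, n = 3 per group), the secreted trefoil peptide TFF1 from 729 ± 119 to 3712 ± 278 (2.36 ± 0.10) and the kinase SGK1 from 1309 ± 31.6 to 5322 ± 365 (2.02 ± 0.06). The chemokine receptor ACKR3 rose from 1447 ± 27.8 to 5480 ± 426 (1.92 ± 0.07), the complement inhibitor CD59 from 931 ± 99.3 to 3371 ± 266 (1.86 ± 0.09) and HOPX, a homeodomain protein, from 1438 ± 126 to 5054 ± 643 (1.81 ± 0.09). VE-cadherin (CDH5), best known in endothelium, rose from 2463 ± 80.0 to 7298 ± 350.0 (1.57 ± 0.06), while the endothelial markers PECAM1 and VWF did not pass the threshold (0.20 and 0.41). On the other side, NANOS1, an RNA-binding protein of germ cells, went from 997 ± 33.9 to 302 ± 12.8 (−1.72 ± 0.10), the FGF signalling inhibitor IL17RD from 513 ± 18.8 to 160.3 ± 11.7 (−1.68 ± 0.14), the Wnt pathway repressor TCF7L1 from 452 ± 39.4 to 152 ± 43.8 (−1.61 ± 0.20) and the collagen receptor subunit ITGA2 from 673 ± 47.4 to 287 ± 10.3 (−1.23 ± 0.11). The groups did not overlap for any of these genes except PECAM1 and VWF.

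The array's own control probe set for the human ISGF3A transcript, which is STAT1, gave a lower 3′ signal after 8-Br-cAMP. It was 3222 ± 75.5 on untreated and 1806 ± 57.2 on 8-Br-cAMP arrays (two-sided exact permutation p = 0.1, the smallest possible). Unlike the spike-ins, it measures a transcript of the cells themselves, so its change need not be technical. The hybridization spike-ins, added after labelling, were 0.15 higher on the log2 scale on 8-Br-cAMP arrays (exact permutation p = 0.1), and the poly-A spike-ins differed by −0.06 (exact permutation p = 0.8).

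GREB1 and TFF1, both known as estrogen-responsive in breast cells, were among the larger rises, and a hypothesis was that estrogen-responsive genes rose more widely, given that aromatase CYP19A1 rose as well. A list of other estrogen-responsive genes was written before it was tested, though values of a few members, such as CA12, had been seen on other lists. Of 18 tested, 5 rose and 6 fell, with a median log2 change of −0.33, and camera, which compares the list with other genes, gave p = 0.655, while an exact permutation of the arrays, added after the camera result was seen, gave p = 0.2. The permuted value was the mean log2 signal of the list minus that of all tested genes, which was 0.39 on untreated and 0.30 on 8-Br-cAMP arrays. A wider rise was not seen on this list. What GREB1 and TFF1 share here stays open.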
